A study of Mus musculus with 35 samples.

How the data were processed

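RNA was extracted from colon tissue with TRIzol and sequencing libraries were made with the VAHTS Universal V6 kit, per the labels' protocols. The submitters' processing notes name fastp for read trimming, HISAT2 for alignment and HTSeq for counting, without versions, and the mouse build mm10. The gene annotation, the strand setting, the handling of reads shared between genes and the test used by the study are not given in the sources used here. Reads from overlapping or antisense genes and from close paralogs could therefore be split in ways that are unknown.

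The authors deposited a table of 28366 genes for 35 libraries, 1 column per sample. No header names the unit. The deposited values were taken as FPKM, fragments per kilobase of gene and per M reads, because they were not whole numbers, their sums differed between libraries (438877 to 500996), and low values were whole multiples of a step that depended on gene and library. Of 12864 genes that stayed below 1 FPKM, 98.1% lay on such steps within 0.02 reads. With gene spans in place of exon lengths, 565 genes piled up at 1 depth, as genes without introns would, and that depth gave totals of 32.5 to 41.1 M reads per library (36.7 to 41.1 in WT, 38.3 to 40.8 in HO and 32.5 to 40.8 in DHO). The 10 genes with the highest values held 13.6% to 18.6% of a library's sum. No library pair had identical values. The pair with the highest correlation, DHO replicates 4 and 5, had a chi-square per gene of 3.03 over 4849 genes. The lowest chi-square per gene of any pair was 2.95, so no library was taken for a repeat of another. Columns were assigned to samples by the sample names in the labels. The labels do not say whether the libraries of a group come from separate mice, so p-values measure the spread between these libraries, which may be partly technical.

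Genes with at least 0.5 FPKM in at least 11 libraries were tested, 13071 in all. Values were scaled by a trimmed mean of log ratios (TMM, 30% trimmed by ratio and 5% by level, without count weights) and tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the variance, 1 term for genotype over all 35 libraries and pairwise contrasts. Fold changes are on that log2 scale, which understates the change of low genes, and are given with their standard errors. Group levels are means and SDs of scaled FPKM. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes below 0.05 passed. The plan written before the data were examined assumed counts and named a count test, its filter and TMM scaling. Because the file held FPKM, limma took the place of the count test, and the filter and the form of TMM were set after the file was seen. A fit on the FPKM as deposited had been run by then, and its counts are given beside the others.

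The 41 gene lists were fixed before the data were examined and 38 had at least 5 tested members. The list of mitochondrial genes used other symbols than the table and had none matched, and the lists of pancreas and sex-linked genes had 2 and 4 tested members. Lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. Lists overlap in members, and markers can be expressed by more than 1 cell type. The genes named were chosen by a rule fixed beforehand: the 10 largest rises and 10 largest falls in HO vs WT and DHO vs HO, and 5 each in DHO vs WT, among genes that passed with a mean of at least 1 FPKM (the rule said CPM) and a symbol that is no predicted model, then Map3k7, Ripk1, Tradd, Ripk3, Mlkl, Casp8, Tnf and Tnfaip3, and up to 4 members with the smallest p from each list. Coordinates come from the RefSeq annotation of GRCm38.p6, which is the assembly of mm10.

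The procedure was tested on simulated data before use. Log2 values for 13071 genes were drawn, each gene independently, from normal distributions with the real mean of WT and the real SD of each group. Of these genes 200 were changed. For HO vs WT 96% of genes changed by 2-fold and 50% of those changed by 1.25-fold were recovered, and 19.5% of 210 calls were false. For DHO vs HO the values were 96%, 50% and 10.4% of 183 calls. For DHO vs WT they were 98%, 44% and 0.6% of 166 calls. The values drawn had a different SD in each group, while the fit takes 1 SD per gene for all groups. With HO the widest group, its contrasts then get standard errors that are too small, and DHO vs WT gets ones that are too large. Fitting only the groups compared moved the shares to 9.7%, 1.9% and 4.8%. The 9.7% left for HO vs WT was not traced further. Real genes moved together, with an estimated correlation of 0.86 in the type I and III interferon list. The shares of false calls from independent genes therefore need not hold for the real comparisons.

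Alternatives were the scaling (RLE, or FPKM as deposited), the filter, the pseudocount (0.1 and 0.5), the libraries in the fit, sample quality weights, covariates, the threshold and leaving out each library. The Y-linked score was the mean log2 level of Ddx3y, Eif2s3y, Kdm5d and Uty. It ran from 1.903 to 2.835, so every library held Y-linked reads. Ddx3y (0.38 ± 0.09) and Eif2s3y (0.48 ± 0.12) passed in HO vs WT, and Kdm5d and Uty did not. As a covariate the score can thus take up part of the genotype difference, and a lower count with it does not show an effect of sex. Alternatives without WT replicates 10 to 12, without HO replicates 8 to 12, and with posterior Hox or clock scores as covariates were added after seeing the data. Random regroupings were drawn with fixed seeds, 100 per comparison. Nothing was paired, because replicate numbers follow only the order of the samples. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the depth estimates and plots.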

Results

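Bulk RNA sequencing measured gene expression in colon tissue of mice at day 3 after the start of gene deletion by tamoxifen, given as 3 daily intraperitoneal injections of 80 mg/kg. TAK1, encoded by Map3k7, is a kinase that relays signals from TNF and other receptors and restrains cell death. The 35 libraries fell into 3 genotypes. Control mice carrying the floxed Tak1 allele formed the WT group (n = 12), and mice with TAK1 deleted in intestinal epithelial cells formed the HO group (n = 12). The DHO group (n = 11) had the same deletion together with the D138N change on both copies of Ripk1, which removes the kinase activity of RIPK1. The study asked what role this kinase plays in colitis after the loss of TAK1. The deposited values gave between 9992 and 11993 genes at 1 FPKM or more per library. The spacing of the low values implied totals of 32.5 to 41.1 M reads per library. At that depth 1 read on a gene of 2 kb corresponded to 0.0122 to 0.0154 FPKM.

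The HO libraries differed from the others and from each other. On the first principal component, which held 52% of the variance, the 12 WT libraries lay between -24.69 and -9.02 and the 11 DHO libraries between -23.63 and -10.83. The 12 HO libraries lay between -5.51 and 105.42, with an SD of 38.75 against 4.98 in WT and 4.42 in DHO. HO replicates 8, 9, 10, 11 and 12 were the farthest out, from 45.27 to 105.42. WT replicates 10, 11 and 12 lay lowest on the second component, at -30.13, -28.47 and -23.58, next to HO replicates 12 and 8 at -22.33 and -22.16.

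**Figure D1:**
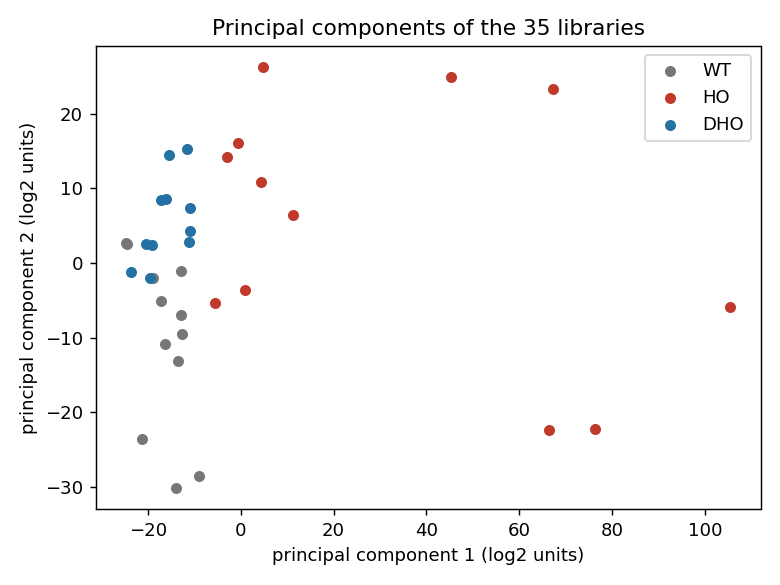
Scores of the 35 libraries on the first (horizontal) and second (vertical) principal components of the log2 values, 1 point per library, coloured by genotype. The HO libraries reach from -5.51 to 105.42 on the first component, and all WT and DHO libraries lie at -9.02 or lower.

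The level of Map3k7 (chromosome 4, 31963492 to 32023470, GRCm38.p6) over the whole gene was 9.82 ± 1.14 FPKM in WT (SD, n = 12), 10.8 ± 1.19 in HO (n = 12) and 9.34 ± 0.487 in DHO (n = 11). The HO vs WT difference, a log2 fold change of 0.13 ± 0.06 (SE), did not pass limma's test (adjusted p = 0.0755), and 9 of 12 HO libraries lay above the WT mean on the log2 scale. Single libraries ranged from 7.838 to 11.601 FPKM in WT, from 8.605 to 12.441 in HO and from 8.611 to 10.115 in DHO. The labels do not say which exons were removed, and the tissue holds cells outside the epithelium, so this gene-level value does not check the deletion. Ripk1 (chromosome 13, 34002225 to 34035170) was at 3.55 ± 0.322 FPKM in WT, 5.49 ± 2.08 in HO and 3.63 ± 0.455 in DHO.

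Loss of TAK1 in the epithelium was compared with control to find what the deletion alone changed. Inflammatory and interferon-induced genes rose in HO, and the largest falls included single genes of epithelial metabolism and transport. Tnf, the cytokine (chromosome 17, 35199367 to 35202007), averaged 30.2 ± 44.8 FPKM in HO and 0.711 ± 0.42 in WT (SD, n = 12 each), a log2 fold change of 2.98 ± 0.47 (adjusted p = 1.13e-05). Cxcl10, an interferon-induced chemokine, averaged 463 ± 756 against 2.82 ± 2.28 FPKM, and single HO libraries ranged from 2.743 to 2404.238. Leaving out HO replicate 11 changed the HO means to 19 ± 23.6 FPKM for Tnf and 287 ± 466 for Cxcl10. Cyp2c55, a cytochrome P450 of colonic epithelium (chromosome 19, 39006940 to 39042690), fell from 387 ± 157 to 76.8 ± 73.9 FPKM.

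Of 13071 genes tested, 5510 passed in HO vs WT, 2759 higher and 2751 lower, and 469 of these changed at least 2-fold, 395 higher and 74 lower. The genes with the largest rises were Clca4b (5.17 ± 0.57 log2, SE), Cxcl10 (4.37 ± 0.81), Trim15 (4.29 ± 0.39), Iigp1 (4.24 ± 0.61), Nos2 (4.19 ± 0.62), Gbp2 (4.02 ± 0.64), Igtp (3.80 ± 0.55), Ifi47 (3.68 ± 0.60), Mt2 (3.62 ± 0.36) and Tgtp1 (3.56 ± 0.60). Iigp1, Igtp, Ifi47, Tgtp1 and Gbp2 are interferon-induced GTPases of host defence, Nos2 is the inducible nitric oxide synthase, and Mt2 is a metallothionein. The largest falls were those of Cyp2c55 (-3.19 ± 0.50), Tppp (-2.42 ± 0.25), Mettl7a2 (-2.22 ± 0.25), Tppp3 (-2.14 ± 0.19), Cpm (-1.91 ± 0.23), Pck1 (-1.84 ± 0.23), Scd2 (-1.80 ± 0.30), Slc34a2 (-1.79 ± 0.36), Gstm3 (-1.75 ± 0.30) and Igfbp2 (-1.55 ± 0.21). Pck1 is a key enzyme of gluconeogenesis, Scd2 desaturates fatty acids and Slc34a2 carries phosphate. On the log2 scale all 12 HO libraries lay on the stated side of the WT mean for each of these 20 genes, except Mettl7a2 with 11. Clca4b, Tgtp1, Cyp2c55, Mt2 and the Gbp, Ly6 and Saa genes belong to families of similar sequence, and how shared reads were counted is not given in the sources used here, so their levels are uncertain.

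Genes of the death pathways rose in HO. Of 44 tested members of the list for cell death and TNF receptor signalling, 29 rose and 3 fell (31 and 3 when adjusted over the list alone), and camera placed the list up (adjusted p = 7.23e-08; adjusted p = 0.76 with an estimated correlation). Ripk3, the kinase that triggers necroptosis (chromosome 14, 55784995 to 55788857), was at 52.3 ± 57.4 FPKM in HO and 7.69 ± 1.19 in WT (adjusted p = 1.28e-05). Mlkl, the effector of necroptosis, rose by 1.84 ± 0.34 and Casp8, the initiator caspase of death receptors, by 1.51 ± 0.22. Zbp1, a nucleic acid sensor that engages RIPK3, rose by 2.75 ± 0.38 and Gsdmd, which forms the pores of pyroptosis, by 1.12 ± 0.18. Ripk1 itself rose by 0.46 ± 0.10 (adjusted p = 0.000409), and Tnfaip3, which encodes the NF-kB inhibitor A20, by 1.26 ± 0.28. For the TNF receptor adaptor Tradd, HO vs WT gave a log2 change of 0.07 ± 0.10 (adjusted p = 0.59), and with FPKM as deposited -0.18 (adjusted p = 0.0282). With that scaling 21 members of the death list rose and 9 fell. Without HO replicates 8 to 12, a choice made after seeing the data, 20 rose and 0 fell.

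Interferon genes moved together. In HO vs WT 31 of 32 tested genes of the type I and III interferon list rose and 0 fell, and the same 31 and 0 stood when adjusted over the list alone (camera adjusted p = 1.92e-17; adjusted p = 0.76 with an estimated correlation). Irf9, a transcription factor of interferon signalling, rose from 13.5 ± 3.77 to 35.6 ± 9.42 FPKM. Of 32 genes of the interferon gamma and MHC class II list, 28 rose and 0 fell, also over the list alone (camera adjusted p = 2.99e-15; adjusted p = 0.76 with an estimated correlation). Irgm2 rose by 2.72 ± 0.38 log2. Without HO replicates 8 to 12, 26 and 23 members of these lists rose, with medians of 1.06 and 1.34 against 2.03 and 2.66 with all libraries.

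NF-kB targets, cytokines and antimicrobial genes followed. Of 30 NF-kB targets 22 rose and 0 fell in HO, as over the list alone (camera adjusted p = 9.17e-07; adjusted p = 0.788 with an estimated correlation), among them Nfkbia, the inhibitor of NF-kB (1.61 ± 0.26 log2), Irf1 (1.81 ± 0.28) and the neutrophil chemokine Cxcl1 (2.45 ± 0.41). Of 20 cytokines and chemokines 14 rose and 2 fell (adjusted p = 0.00117; adjusted p = 0.788 with an estimated correlation). Of 24 antimicrobial and acute phase genes 16 rose and 2 fell (adjusted p = 1.17e-05; adjusted p = 0.76 with an estimated correlation). Duoxa2, needed for the epithelial oxidase DUOX2, rose from 19.3 ± 8.13 to 173 ± 246 FPKM, or to 107 ± 92.1 without HO replicate 11. Without HO replicates 8 to 12 the counts of rises in these lists were 9, 8 and 11.

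Markers of other cell types changed in different directions. Of 10 neutrophil markers 6 rose and 0 fell (7 over the list alone; adjusted p = 0.00391; adjusted p = 0.804 with an estimated correlation), and 2 rose without HO replicates 8 to 12. Ltf, a neutrophil granule protein, was at 20.7 ± 36.4 FPKM in HO (12.2 ± 22.7 without HO replicate 11) and 0.55 ± 0.132 in WT, while Ly6g stood at 262 ± 76.6 FPKM in WT, so colon tissue itself gave reads for that marker. Of 26 monocyte and macrophage markers 5 rose and 3 fell (adjusted p = 0.524; 2 and 5 with FPKM as deposited), with Cd14 higher by 1.10 ± 0.23 and Cx3cr1 lower by 0.75 on the log2 scale (-0.75 ± 0.17). The T and NK cell list (adjusted p = 0.953) and the B and plasma cell list (adjusted p = 0.196) did not pass. Of 19 B and plasma cell markers 2 rose and 5 fell, with 0 falls over the list alone and 11 with FPKM as deposited. Genes of fibroblasts and matrix fell, 19 of 27 against 1 that rose, also over the list alone (adjusted p = 1.03e-05; adjusted p = 0.788 with an estimated correlation). Col1a1 went from 54.8 ± 16.5 to 23.2 ± 11 FPKM and Col3a1 from 151 ± 37.7 to 70.7 ± 27.7. Smooth muscle markers fell in 10 of 24 cases and rose in 1 (adjusted p = 0.00598; adjusted p = 0.896 with an estimated correlation), and without HO replicates 8 to 12 0 of them passed, with a list median of -0.28 against -0.36 with all libraries. With FPKM as deposited 18 smooth muscle markers fell and 0 rose.

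Further lists passed by camera in HO vs WT, and bulk tissue does not tell which cells they came from. Of 27 genes of the regeneration and fetal-like list 14 rose and 2 fell (adjusted p = 0.00391; adjusted p = 0.896 with an estimated correlation). Ly6a, a marker of regenerating epithelium that immune cells also express, rose from 393 ± 130 to 2608 ± 2206 FPKM. Without HO replicates 8 to 12, 4 members rose and 5 fell. The ER stress list had 17 of 29 rises and 1 fall (adjusted p = 3.51e-05; adjusted p = 0.78 with an estimated correlation), or 10 rises and 3 falls with FPKM as deposited, with Hspa5, the main ER chaperone, higher by 0.91 ± 0.17. Tight junction genes gave 14 rises and 2 falls of 25 (adjusted p = 0.00562; adjusted p = 0.896 with an estimated correlation), or 9 and 6 with FPKM as deposited. Glucocorticoid targets gave 10 and 2 of 20 (adjusted p = 0.00053; adjusted p = 0.76 with an estimated correlation), with Fkbp5 higher by 1.19 ± 0.21, and immediate early genes 10 and 2 of 21 (adjusted p = 0.00327; adjusted p = 0.896 with an estimated correlation), with Socs3 higher by 3.08 ± 0.34. With HO replicates 8 to 12 left out, the rises and falls were 7 and 0 of 28 for ER stress, 7 and 1 for tight junctions, 8 and 1 for glucocorticoid targets and 5 and 3 for immediate early genes. Cytosolic ribosomal protein genes had 0 rises and 3 falls of 36 and a median of -0.13 (adjusted p = 0.0165; adjusted p = 0.896 with an estimated correlation). Of these genes 0 fell over the list alone, 0 with RLE scaling, 0 without HO replicates 8 to 12 and 32 with FPKM as deposited, so that count depended on the scaling. Of 40 colonocyte markers 13 rose and 7 fell (11 and 10 with FPKM as deposited), and that list did not pass (adjusted p = 0.28). Of 13 posterior Hox genes, whose levels mark position along the gut, 0 rose and 5 fell, among them Hoxa10 (-0.51 ± 0.09). As a list they did not pass camera (adjusted p = 0.196). No camera call of any comparison held with an estimated correlation. By fry the lists that camera placed in HO vs WT also passed, except smooth muscle (adjusted p = 0.1) and ribosomal protein genes (adjusted p = 0.223). Fry gave adjusted p = 4.94e-05 for type I and III interferon, 0.000328 for cell death and 0.00386 for NF-kB targets.

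The spread of the HO libraries and the scaling limited these counts. In simulated data with the real spread of each group but genes drawn independently, 41 of the 210 calls made for HO vs WT were unchanged genes. On the real data, fitting HO and WT alone gave 4572 calls. There were 3108 calls without HO replicates 8 to 12 and 3327 with the Y-linked score as covariate. With FPKM as deposited the median over all genes moved from -0.01 to -0.19, and 1292 genes were higher and 5774 lower.

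**Figure D2:**
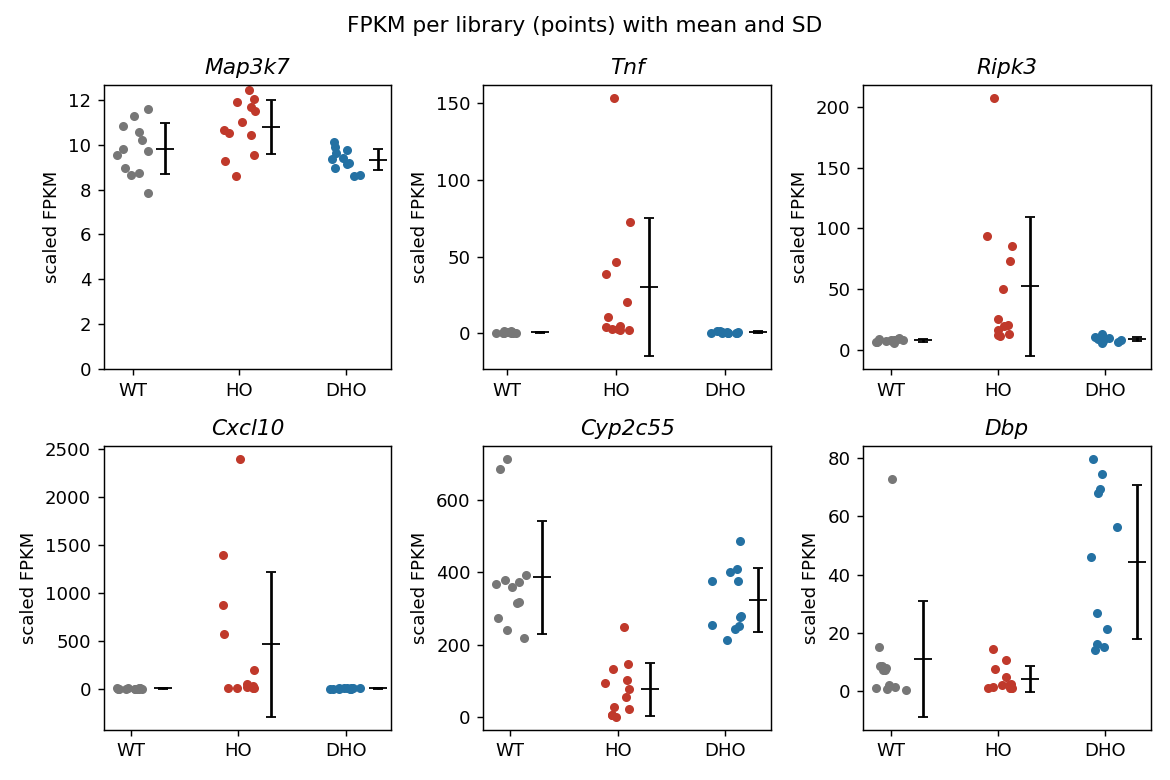
FPKM after scaling, 1 point per library, for 6 genes in WT (n = 12), HO (n = 12) and DHO (n = 11), with linear axes and black bars for the mean and SD. Tnf in DHO, at a mean of 0.785 FPKM, lay near its WT mean of 0.711, while the HO libraries spread up to 153.247.

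The DHO vs HO comparison asked what the kinase-dead Ripk1 allele changed on the TAK1-deleted background, the question the design names. Inflammatory genes that were high in HO were lower in DHO, and several of the genes with the largest falls in HO were higher. The lists of colonocyte markers (8 of 40 rose and 7 fell; adjusted p = 0.762) and of PPAR and fatty acid oxidation genes (5 of 23 rose and 7 fell; adjusted p = 0.696) did not pass. With FPKM as deposited the rises and falls were 13 and 6 for the first and 5 and 4 for the second. Tnf fell from 30.2 ± 44.8 FPKM in HO (n = 12; 19 ± 23.6 without HO replicate 11) to 0.785 ± 0.597 in DHO (SD, n = 11), a log2 change of -2.95 ± 0.48 (adjusted p = 3.17e-05). Ripk3 fell from 52.3 ± 57.4 to 8.79 ± 1.92 FPKM, and Cyp2c55 rose from 76.8 ± 73.9 to 325 ± 87.8.

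In DHO vs HO 4850 genes passed (3987 with only DHO and HO fitted), 2303 higher and 2547 lower in DHO, with 98 and 360 of them changed at least 2-fold. The largest falls were Clca4b (-5.89 ± 0.58 log2), Cxcl10 (-4.07 ± 0.83), Nos2 (-4.05 ± 0.64), Mt2 (-3.79 ± 0.37), Trim15 (-3.66 ± 0.40), Ubd (-3.53 ± 0.72), Iigp1 (-3.34 ± 0.63), Sprr1a (-3.25 ± 0.58), Ifi47 (-3.20 ± 0.62) and Igtp (-3.19 ± 0.56). Sprr1a is a cornified envelope protein found in regenerating epithelium. The largest rises were Dbp (3.24 ± 0.50), Cyp2c55 (2.99 ± 0.52), Mettl7a2 (2.39 ± 0.25), Tppp (2.08 ± 0.26), Scd2 (1.92 ± 0.31), Pck1 (1.91 ± 0.24), Cyp2c68 (1.89 ± 0.39), Slc20a1 (1.75 ± 0.22), Gstm3 (1.64 ± 0.31) and Dio1 (1.64 ± 0.34). Dbp is a transcription factor that the circadian clock drives. On the log2 scale all 11 DHO libraries lay on the stated side of the HO mean for each of these 20 genes. Casp8 fell by 1.27 on the log2 scale (-1.27 ± 0.23), Mlkl by -1.61 ± 0.35, Tnfaip3 by -1.18 ± 0.28 and Ripk1 by -0.44 ± 0.10, and Tradd differed by -0.03 ± 0.10 (adjusted p = 0.864). Map3k7 was lower by a log2 change of -0.18 ± 0.06 (adjusted p = 0.0136).

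The lists that rose in HO fell in DHO vs HO. All 32 interferon gamma and MHC class II genes fell (camera adjusted p = 3.32e-16; adjusted p = 0.612 with an estimated correlation), as did 31 of 32 type I and III interferon genes (adjusted p = 2.85e-18; adjusted p = 0.612 with an estimated correlation) and 22 of 30 NF-kB targets (adjusted p = 1.77e-09; adjusted p = 0.612 with an estimated correlation). The counts adjusted over the list alone were 32, 32 and 23. Of 44 cell death genes 26 fell and 4 rose (adjusted p = 3.38e-05; adjusted p = 0.662 with an estimated correlation), with Zbp1 at -2.22 ± 0.39. Without HO replicates 8 to 12 the falls in these lists numbered 22, 25, 12 and 10. Monocyte and macrophage markers fell in 14 of 26 cases (adjusted p = 0.000597; adjusted p = 0.702 with an estimated correlation), for example Cd14 at -1.14 ± 0.24, and 2 fell without those HO libraries and 8 with FPKM as deposited, where 1 rose. Of 27 regeneration genes 14 fell and 2 rose (adjusted p = 0.000597; adjusted p = 0.702 with an estimated correlation), and 4 each way without them. Camera also placed down the lists of cytokines (14 of 20 fell), antimicrobial genes (16 of 24), neutrophil markers (7 of 10), ER stress (15 of 29), immediate early genes (13 of 21), glucocorticoid targets (12 of 20), tight junctions (11 of 25), T and NK cells (4 of 14) and enteroendocrine cells (3 of 16). With an estimated correlation their adjusted p lay between 0.612 and 0.739. With those HO libraries left out, the falls in these lists, in the same order, numbered 6, 9, 2, 6, 3, 5, 4, 0 and 0, and the median of the enteroendocrine list was 0.12 against -0.31 with all libraries. By fry the lists of tight junctions (adjusted p = 0.0511), T and NK cells (adjusted p = 0.0786) and enteroendocrine cells (adjusted p = 0.105) did not pass.

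Other lists rose in DHO vs HO. Of 24 cholesterol synthesis genes 13 rose and 1 fell (adjusted p = 0.00078; adjusted p = 0.612 with an estimated correlation), among them Dhcr7, the last enzyme of the pathway (1.09 ± 0.20), and Mvd (1.04 ± 0.17). Of 13 posterior Hox genes, whose levels mark position along the gut, 7 rose and 0 fell (adjusted p = 0.00427; adjusted p = 0.612 with an estimated correlation), with Hoxa9 at 0.68 ± 0.10. Among 19 clock genes 10 rose and 4 fell (adjusted p = 0.0118; adjusted p = 0.612 with an estimated correlation). Per3 rose by 1.27 ± 0.20 and Nfil3, a repressor that opposes Dbp, fell by 1.81 on the log2 scale (-1.81 ± 0.20). Smooth muscle markers (8 of 24 rose; adjusted p = 0.00829) and ribosomal protein genes (4 of 36 rose; adjusted p = 0.00427) were also placed up, with adjusted p = 0.739 and 0.75 with an estimated correlation. Of the ribosomal protein genes 0 rose over the list alone and 12 with FPKM as deposited. Of 27 fibroblast and matrix genes 11 rose and 3 fell (adjusted p = 0.0262; adjusted p = 0.75 with an estimated correlation). By fry the lists of smooth muscle (adjusted p = 0.147), ribosomal protein (adjusted p = 0.165) and fibroblast genes (adjusted p = 0.18) did not pass. The rises without HO replicates 8 to 12 numbered 8 for cholesterol synthesis, 2 for posterior Hox genes, 10 for the clock, 0 for smooth muscle, 0 for ribosomal proteins and 6 for fibroblasts. Fewer genes passed in other settings chosen after seeing the data, 2179 with the posterior Hox score as a covariate, 2944 with the clock score and 2210 without HO replicates 8 to 12. With FPKM as deposited 3252 genes were higher and 1408 lower, and the median over all genes was 0.11.

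**Figure D3:**
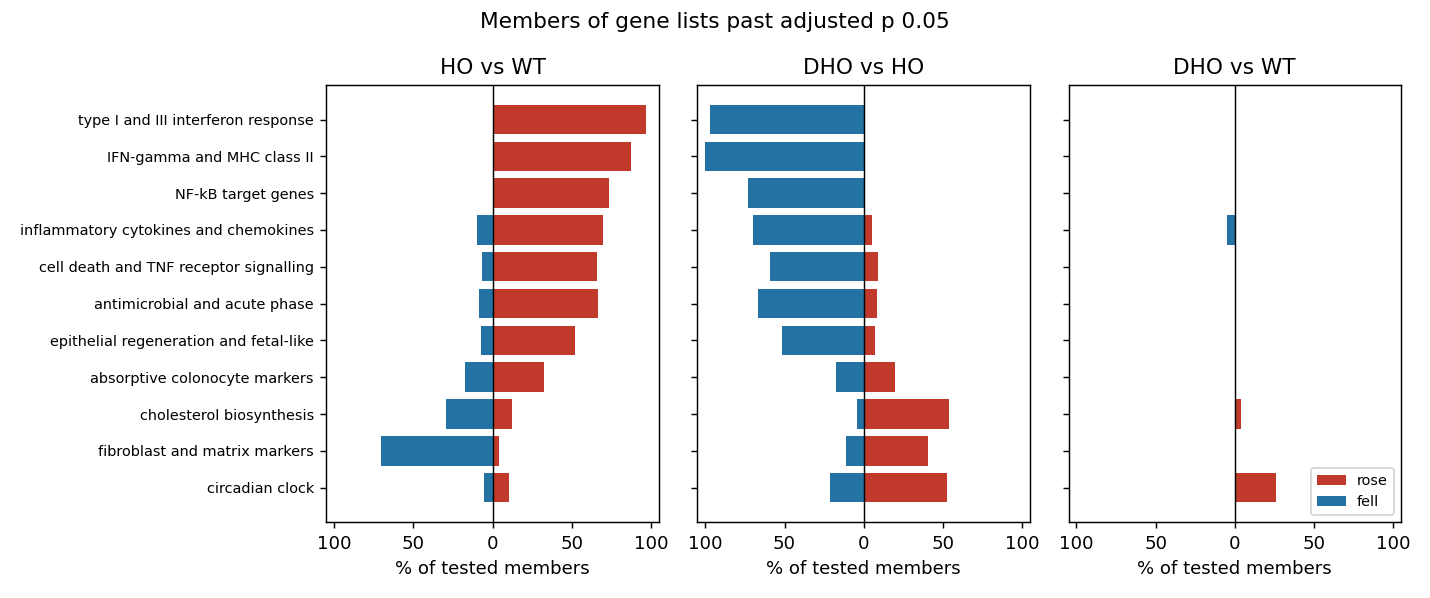
Share of the tested members of 11 gene lists that rose (red, to the right) or fell (blue, to the left) past an adjusted p of 0.05 in each comparison, in percent. Of 32 interferon gamma and MHC class II genes, 28 rose in HO vs WT, 32 fell in DHO vs HO and 0 passed in DHO vs WT. All 3 groups were fitted together, so the standard errors of DHO vs WT include the spread of HO.

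The set of genes changed by the deletion and moved back in DHO was then counted. Of the 5510 genes that passed in HO vs WT, 3626 (65.8%) passed in DHO vs HO in the opposite direction, 1884 that were high and 1742 that were low in HO, and 0 passed in the same direction. In DHO vs WT 111 of the 5510 passed with the sign they had in HO, 21 of them also among the 3626. Another 1794 passed in neither. The DHO vs WT calls come from the fit of all 3 groups, whose standard errors include the spread of HO. In that fit 182 genes passed in DHO vs WT, against 1623 with WT and DHO fitted alone. The 111 may thus be too low and the 1794 too high. HO vs WT and DHO vs HO share the HO libraries, so part of a count such as 3626 arises by chance. Independent lists of these sizes would share 537.6 genes high and 484.7 low in HO. In 20 simulations of a DHO group that did not differ from HO the median count was 0 and the highest 3143. With the HO libraries split at random into groups of 6, one for each comparison, a median of 58.5% of the genes high in HO and 50.5% of those low moved back over 20 splits, with lowest values of 12.9% and 12.4%. The count without HO replicates 8 to 12 was 1411.

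**Figure D4:**
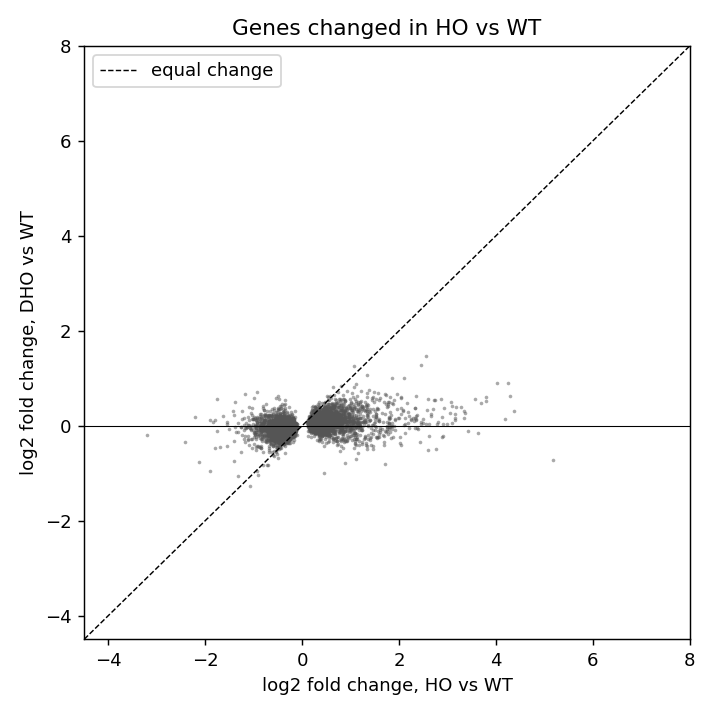
Log2 fold change in HO vs WT (horizontal) against that in DHO vs WT (vertical), 1 point for each of the 5510 genes that passed in HO vs WT. The dashed line marks equal change, and the points lie near 0 on the vertical axis, with 7.8% (bootstrap SE 4.3) of the change left over the 469 genes that changed at least 2-fold. These genes were chosen by their HO vs WT change and both axes share the WT libraries, so the share may be biased in a way that the SE leaves out.

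The fold changes of HO and DHO against the same WT libraries had a Pearson correlation of 0.289 across genes, which are not independent replicates, and a covariance of 0.0237. Simulated groups that did not differ from WT gave a median correlation of 0.35 and a median covariance of 0.0033, at most 0.0112. With WT split at random between the comparisons the median correlation was 0.201 and the median covariance 0.0185. The share of the HO change left in DHO, estimated as a slope with split WT libraries over the genes called in HO, had a median of 9% and ranged from 3.5% to 14.6% over 20 splits. The genes were called on the same HO values that the slope divides by, so it can understate the share.

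The DHO vs WT comparison asked what remained different from control in mice with both changes. Clock genes gave 5 calls, and Dbp had the largest rise. Dbp (chromosome 7, 45705100 to 45710203) was at 44.3 ± 26.3 FPKM in DHO (SD, n = 11) and 11.1 ± 19.9 in WT (n = 12), a log2 change of 2.61 ± 0.50 (adjusted p = 0.00703), with all 11 DHO libraries above the WT mean on the log2 scale. WT replicate 9 stood at 72.654 FPKM, within the DHO range of 14.249 to 79.812, and without it the WT mean was 5.53 ± 4.71. For Dbp, DHO vs WT did not pass by limma in every setting, with adjusted p from 0.000191 to 0.861 over all of them. Without WT replicates 10 to 12 it did not pass (2.14 log2, adjusted p = 0.0549), and the setting at 0.861 was farther from passing. Tnf (0.03 ± 0.48, adjusted p = 0.982), Ripk3 (0.16 ± 0.33, adjusted p = 0.854), Mlkl (0.23 ± 0.34, adjusted p = 0.794), Casp8 (0.25 ± 0.23, adjusted p = 0.628), Tnfaip3 (0.08 ± 0.28, adjusted p = 0.919), Ripk1 (0.02 ± 0.10, adjusted p = 0.942), Tradd (0.04 ± 0.10, adjusted p = 0.869) and Map3k7 (-0.06 ± 0.06, adjusted p = 0.658) did not pass in the fit of all 3 groups, whose standard errors include the spread of HO. For Casp8, DHO vs WT passed with only WT and DHO fitted (0.25 log2, adjusted p = 0.0275; from 0.0275 to 0.89 over all settings), and its level was 38 ± 4.81 FPKM in DHO and 31.8 ± 3.83 in WT, while the other 7 genes did not pass in that fit.

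In DHO vs WT 182 genes passed, 136 higher and 46 lower, and 13 changed at least 2-fold. The largest rises were Dbp, Ciart (1.55 ± 0.37 log2), Ly6m (1.48 ± 0.37), Tef (1.40 ± 0.28) and Gda (1.28 ± 0.21). Ciart and Tef belong to the clock and its output, and Gda is guanine deaminase. The largest falls were Spon2 (-1.06 ± 0.26), Rab3b (-1.01 ± 0.17), Cpm (-0.96 ± 0.24), E2f2 (-0.84 ± 0.16) and Tppp3 (-0.77 ± 0.19), of which Cpm and Tppp3 were also among the largest falls in HO. Between 9 and 11 of the 11 DHO libraries lay on the stated side of the WT mean on the log2 scale for these 10 genes. Of 19 clock genes 5 rose and 0 fell (11 and 4 over the list alone; camera adjusted p = 8.34e-06; adjusted p = 0.643 with an estimated correlation), and fry gave an adjusted p of 0.0345. Nr1d2 rose from 9.75 ± 5.8 to 23.6 ± 7.05 FPKM and Per3 from 1.69 ± 0.966 to 4.28 ± 2.57.

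By limma 0 of the 32 type I and III interferon genes passed in DHO vs WT, with 0 at an unadjusted p below 0.05 and a median of 0.05. In this fit of all 3 groups the standard errors include the spread of HO, so the counts cannot exclude small changes. Of the 32 interferon gamma genes 0 passed and 1 did so unadjusted. Of 30 NF-kB targets 0 passed, with 1 higher and 4 lower unadjusted, and of 44 death genes 0 passed, with 7 higher unadjusted and a median of 0.09 (camera adjusted p = 0.00937; adjusted p = 0.926 with an estimated correlation). In the fit without HO replicates 8 to 12, a setting chosen after seeing the data, 9 death genes rose and 1 fell, 1 NF-kB target rose and 6 fell, while 1 gene of each interferon list rose, 10 of 26 macrophage markers fell and 5 fibroblast genes fell. Camera also placed 19 B and plasma cell markers down (median -0.52, 0 passed and 12 fell over the list alone; adjusted p = 1.38e-06; adjusted p = 0.748 with an estimated correlation), as it did 27 fibroblast genes (median -0.36, 0 passed; adjusted p = 4.34e-06; adjusted p = 0.748 with an estimated correlation). Of 26 macrophage markers 1 passed, Apoe at -0.51 ± 0.13 (list adjusted p = 7.97e-06; adjusted p = 0.748 with an estimated correlation). The lists of proliferation (adjusted p = 8.34e-06), T and NK cells (adjusted p = 0.00084) and endothelium (adjusted p = 0.00761) were placed down. Those of cholesterol synthesis (adjusted p = 8.34e-06; 1 gene passed and 9 rose over the list alone), colonocytes (adjusted p = 0.00431) and posterior Hox genes (adjusted p = 0.0438) were placed up. With an estimated correlation their adjusted p lay between 0.748 and 0.926. By fry only the clock list passed in DHO vs WT, and B and plasma cell markers (adjusted p = 0.174), fibroblast genes (0.319), macrophage markers (0.319) and proliferation genes (0.425) did not.

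The DHO vs WT count depended strongly on the setting. The shared estimate of spread includes the HO libraries, and 1623 genes passed when WT and DHO were fitted alone, 3116 with sample quality weights, 14 with the Y-linked score and, in settings chosen after seeing the data, 36 without WT replicates 10 to 12 and 3 with the clock score as covariate. The median absolute log2 change of the 182 genes was 0.37, and 0.36 with the weights, 0.30 with the Y-linked score, 0.35 without those WT libraries and 0.29 with the clock score. With FPKM as deposited 46 genes were higher and 57 lower, and leaving out 1 library gave from 48 (without WT replicate 4) to 321 (without WT replicate 9).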

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

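The alternatives without WT replicates 10 to 12, without HO replicates 8 to 12, with the posterior Hox score and with the clock score, and the lists with FPKM as deposited, were chosen after the data were seen; the cause of a change was not tested unless stated. For HO vs WT 5510 genes passed, and 3327 with the Y-linked score, 3108 without HO replicates 8 to 12 and 469 with a log2 change of at least 1, a stricter threshold. For DHO vs HO 4850 passed, and 2179 with the Hox score, 2944 with the clock score, 2210 without HO replicates 8 to 12, 458 with a log2 change of at least 1 and 2874 at an adjusted p below 0.01. For DHO vs WT 182 passed, and 103 with FPKM as deposited, 86 with no filter on low values, 1623 with only the 2 groups compared, 3116 with sample quality weights, 14 with the Y-linked score, 3 with the clock score, 36 without WT replicates 10 to 12, 1303 without HO replicates 8 to 12, 13 with a log2 change of at least 1 and 22 at an adjusted p below 0.01. All 182 kept their sign with only the 2 groups compared, with the weights, with the Y-linked score and without HO replicates 8 to 12, and 179 did without WT replicates 10 to 12 and 180 with the clock score. Of the genes that moved back 3626 were counted, and 2141 with weights, 1797 with the Hox score, 1411 without HO replicates 8 to 12 and 2110 at an adjusted p below 0.01. The other settings stayed within 1.5 times these counts.

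Leaving out 1 library at a time gave 4892 to 5894 genes for HO vs WT and 4112 to 5269 for DHO vs HO. For DHO vs WT the range was 48 to 321, and 15 libraries moved it by over 1.5 times: without WT replicates 1, 2, 3, 4, 9, 11 and 12 it was 76, 113, 72, 48, 321, 75 and 73, without HO replicates 10 and 11 it was 279 and 310, and without DHO replicates 2, 3, 4, 5, 7 and 11 it was 97, 89, 88, 58, 67 and 83. For Map3k7, HO vs WT did not pass in any of the settings run for it, and the sign turned with FPKM as deposited (-0.105). Signs also turned for Tradd in HO vs WT with FPKM as deposited (-0.18), for 2 genes in DHO vs HO without HO replicates 8 to 12, among them Neurod1 (0.021), for Hoxd12 in DHO vs HO with the Hox score (-0.076), of which it is part, for Ciart in DHO vs WT with the clock score (-0.098), and for Tef, DHO vs WT with the clock score (-0.015), which holds both. Of 510 results for single genes, 88 no longer passed and 53 newly passed without HO replicates 8 to 12. With sample quality weights these numbers were 53 and 87, with the clock score 72 and 6, with the Hox score 67 and 4, with only the 2 groups compared 24 and 61, with the Y-linked score 45 and 0, with no filter on low values 36 and 1, with the smooth muscle score 31 and 3, with FPKM as deposited 27 and 16, without WT replicates 10 to 12 22 and 5, with a mean of at least 1 FPKM 0 and 5, and with each pseudocount 3 and 2. Of 114 list results, 47 lost their call with an estimated correlation and 18 lost and 1 gained it with fry. DESeq2, surrogate variables and the other count-based forms of the planned settings were not run, since they need counts. No paired analysis was possible because replicate numbers carry no link between libraries. Depth limits genes near 0.0154 FPKM, the value of 1 read on a gene of 2 kb in the shallowest library.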

Other observations

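The tests of the spread of the HO libraries, of the interferon genes, of the clock genes and of the splits of WT and DHO fitted alone were chosen only after the results were seen; the splits of each comparison and the test of DNA next to Ripk1 were planned. The clock test was first a comparison between its gene groups across genes, and was replaced by one across libraries after that value was seen. Further lists did not pass camera in HO vs WT, while single members did by limma. Of 41 proliferation genes 13 fell and 3 rose (camera adjusted p = 0.0922), among them Ccnb2, a cyclin of mitosis, from 17.5 ± 8.81 to 8.56 ± 3.73 FPKM (SD, n = 12 each). Of 19 stem cell and Wnt genes 8 fell and 4 rose (adjusted p = 0.242), with Axin2, a Wnt target, at -0.63 ± 0.13 and Myc at 0.96 ± 0.20 log2 (SE). Of 22 antioxidant and NRF2 targets 9 rose and 8 fell (adjusted p = 0.953), with Nqo1 at -1.20 ± 0.14. Of 23 genes of PPAR signalling and fatty acid oxidation 10 rose and 5 fell (adjusted p = 0.196), with Acadl at 1.29 ± 0.15. Of 25 p53 targets 7 rose and 4 fell (adjusted p = 0.68), with Cdkn1a at 1.16 ± 0.24. Among 22 goblet cell markers 7 rose and 4 fell (adjusted p = 0.535), with Retnlb, an antibacterial goblet cell product, at 52.9 ± 72.6 FPKM in HO and 4.57 ± 9.9 in WT (adjusted p = 0.00473), or 1.82 ± 2.8 without WT replicate 11. With FPKM as deposited 0 proliferation genes rose and 22 fell, 4 stem cell and Wnt genes rose and 12 fell, and the falls outnumbered the rises in the lists of NRF2 (5 rose and 9 fell), PPAR (5 and 8), p53 (4 and 11) and goblet cell genes (2 and 7).

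No grouping by chance gave as many genes in the comparisons. In 1 of 100 splits of the libraries, the real one, 5510 genes passed for HO vs WT, and the highest other split gave 3395. For DHO vs HO the real split, again 1 of 100, gave 4850 and the highest other 2376. A random split that holds the genotypes unevenly keeps part of the genotype difference, so these high counts alone do not show a structure beyond genotype. What produced them was not tested. For DHO vs WT the real split, 1 of 100, gave 182 and the highest other 0, and with WT and DHO fitted alone 1623 and 0 (1 of 100). DNA next to Ripk1 could differ between the lines and give calls in DHO vs WT. Within 10 Mb of Ripk1 2 of 77 tested genes passed against 181 of 13040 with a known position in all, an odds ratio of 1.9 (95% interval 0.22 to 7.22, Fisher's exact p = 0.29). With so few genes this cannot be told apart from no effect.

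The spread of the HO libraries on the first principal component, an SD of 38.75 against 4.98 in WT, may have a technical part. A line on the posterior Hox score fitted within HO left an SD of 26.7, a line on the implied depth 36.3 and a line on the smooth muscle score 39.1, all above 9.96, which is 2 times the WT value. Position along the colon, depth and muscle content thus did not account for the whole spread as such lines, although the Hox score took up part of it. Differences between mice in the extent of deletion or in the course of disease, and batches that the labels do not name, stay open and were not tested.

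The higher interferon genes in HO could come from more immune cells or from a response of resident cells. The 59 macrophage, T, NK, B and plasma cell markers tested had a median log2 fold change of -0.04, far below the median of 2.03 of the interferon list. By list the medians were 0.17 for macrophages, -0.03 for T and NK cells and -0.37 for B and plasma cells. These markers thus did not rise as a set over all HO libraries. The standard error of 0.07 was taken across markers, which moved together (estimated correlations of 0.525, 0.547 and 0.489), and leaves out the spread between libraries. Without HO replicates 8 to 12 the medians were -0.25, -0.19 and -0.30 in the same order. The macrophage median thus rested partly on those replicates. In DHO vs HO 14 of 26 macrophage markers fell and 0 rose, with a median of -0.49. Over all HO libraries a larger share of these cells was not seen. It is not excluded, least of all for macrophages in HO replicates 8 to 12. Neutrophil markers rose. HO replicates 8 to 12 had neutrophil scores of 3.886 to 6.147, and the other HO libraries 1.845 to 2.452. Without those replicates, set apart by their measured values, the neutrophil median was -0.01 with 2 of 9 rising, a drop that the choice made all but certain. In that setting 26 of 32 interferon genes rose with a median of 1.06. This contrast does not test the part played by neutrophils, which stays open. Activation of immune cells without a change in their number also stays open. A response of the TAK1-deleted epithelium is a hypothesis that bulk tissue does not test.

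The clock genes that were higher in DHO than in WT could reflect a difference in the time of day at which tissue was taken, or in the phase of the clock. This bears also on DHO vs HO, where the clock score with -1.647 to 0.142 in HO did not overlap that of DHO. With the score as covariate 2944 genes passed in DHO vs HO, against 4850 without it, and 2464 genes moved back, against 3626. Because the scores do not overlap, the covariate can hardly be told apart from genotype there. The mean of Dbp, Tef, Hlf, Nr1d1, Nr1d2, Per2, Per3 and Ciart was higher in DHO by 1.29 log2, which restates the pattern that prompted the test. The mean of Arntl, Npas2, Clock, Cry1 and Nfil3, which peak at the opposite time, was lower (-0.48, two-sided permutation p = 0.00055), as a shift in phase needs. In the clock list 4 genes had already fallen over the list alone in DHO vs WT, so this is not independent support. It cannot tell a shift in phase from an effect of genotype on the clock. The permutation took libraries as independent, while runs of consecutive libraries had similar clock scores. These went from 0.003 to 0.585 in WT replicates 1 to 6 and from 1.738 to 2.527 in DHO replicates 3 to 8. If such libraries shared a time of collection, the p-value is too small. With the clock score as a covariate 3 genes passed in DHO vs WT, as the median absolute log2 change of the 182 genes went from 0.37 to 0.29 and their median standard error from 0.08 to 0.11. The clock score ranged from -1.68 to 1.985 within WT, with replicate 9 the highest, and from 0.527 to 2.527 within DHO, and the labels give no time of collection, so an effect of genotype on the clock stays open.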
